A study of Micropterus salmoides with 8 samples.

How the data were processed

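Total RNA was extracted from liver with RNA STAT60 and labelled with Cy3 for a 1-colour Agilent array, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, with 4 control and 4 methoxychlor arrays. The deposited scanner files hold Cy3 intensity values from Agilent Feature Extraction 9.5.1.1, per the file headers. The processed intensity is on a linear scale after local background subtraction, detrending and replacement of dim values by surrogates, per the file headers, and was not scaled between arrays. In the deposited file of methoxychlor replicate 4, 100% of the intensity values were rounded to 3 significant digits, against 0.008846% in methoxychlor replicate 3. The deposited value table of the series holds log2 values. Each column followed log2 of the same array's processed signal (r of at least 0.998925, slopes of 0.9795 to 1.025), with column medians of 2.998, 3.007, 3.042 and 3.035 in controls and 2.981 to 3.008 in treated fish. Its direction is therefore that of the signal, and the step that aligned the arrays stays unknown.

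The array held 43803 spots of fish probes and 1417 control spots. Of the 33514 fish probes, 10289 were spotted 2 times and their spots were averaged. Class letters in the probe names divide them into 10289 AF, 7395 AM, 10146 CF and 5684 CM probes. F and M probes of a contig carry opposite strands: 10581 pairs shared at least 20 bases as reverse complements and 3 on the same strand. Between 2 F probes of a contig such overlaps were few, 6 as reverse complements and 3 on the same strand.

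The log2 processed signal minus each array's 75th percentile over fish spots was used, with no pseudocount. Control spots and spots marked as outliers were left out, and probes well above background on at least 4 of the 8 arrays were kept, with at least 2 values per group. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates), with Benjamini-Hochberg adjustment over 17817 probes and a threshold of 0.05. SE values are limma's moderated errors. Single values were compared by exact two-sided permutation over 35 splits. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

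A probe not well above background on every array of a group has only a bound there. The bright group's mean was then set against the dim group's mean of, per array, the higher of the dim probe's own value and the lowest value among probes well above background, and the ratio is given as "at least N-fold".

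The limma step was tested on simulated data: 10 runs on 17486 probes, with the means and within-group spreads of the real probes and 200 changed probes per run. It recovered median log2 changes of 1.02, 2.02 and 3.01 for 2-fold, 4-fold and 8-fold changes, and 4.09% of its calls were false. The simulated probes varied independently, unlike the real ones.

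Before the data were examined, the rule for named genes took the 12 largest differences per direction past the threshold, or the 8 smallest p, among probes with a gene name, with a fixed list of estrogen-response and other genes. It also fixed gene lists and cell type markers for camera and fry. None of these could be applied, because the files pair no probe with a gene name. The 2 probes per direction with the smallest unadjusted p were named in their place.

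The alternatives were normexp background correction with an offset of 50, quantile and median scaling, no filter on dim probes, a filter on all 8 arrays, marked spots kept, eBayes with trend and robust, array weights, a replicate block, the deposited value table, another threshold and leaving out each array. Added after seeing the data were contig means per strand, array weights per group and scaling to 7 bright spike-in controls. Slide and scan could not be fitted as blocks, since each group lay on 1 slide of its own that was scanned separately. The p-values treat the 4 arrays of a group as separate fish, since the labels call them biological replicates, and also hold any slide effect.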

Results

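Liver RNA from male largemouth bass was compared between control fish and fish that had received methoxychlor, an organochlorine insecticide, as 1 intraperitoneal injection of 25 mg/kg. The sample labels place sampling 48 hours after the injection, whereas the series description gives 48 days, and the time was therefore left open. Each group held 4 arrays, which the labels call biological replicates, and each array measured 1 liver sample in a single colour (Cy3). The array carried 33514 fish probes of 60 bases for 15943 assembled contigs. The probes carry contig names and no gene names, and 0 of their IDs matched the 37622 genes of the reference table, so that transcripts are given here by probe and contig and were not placed on the genome.

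Between 23466 and 26646 of the 43803 fish spots were well above background on the control arrays, and between 23063 and 26105 on the methoxychlor arrays. The 75th percentile of the processed signal was 53.11 ± 11 (SD, n = 4) in controls and 47.22 ± 8.14 (SD, n = 4) in treated fish, a difference smaller than the spread between arrays (two-sided exact permutation test, p = 0.4, 0.5 after Benjamini-Hochberg adjustment over 5 array measures). No spot was saturated. The 4 control arrays lay on 1 slide and the 4 methoxychlor arrays on another, so that slide and treatment cannot be told apart. The net local background was 2.252 ± 0.154 (SD, n = 4) on the control slide and 0.7712 ± 0.128 (SD, n = 4) on the methoxychlor slide (exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow, adjusted 0.0715). The control arrays also had more spots marked as outliers, 82 to 747 against 4 to 12 (exact permutation p = 0.0286, adjusted 0.0715). The number of arrays limits the precision of every value below.

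The comparison of methoxychlor with control liver asked which transcripts differed in abundance after the exposure. The probe with the smallest p, UF_Msa_CF_125030 of contig LMB_S454.sd.79.C1, was bright in all 4 treated livers and not well above background in any of the 4 control livers. Its signal was at least 8.36-fold higher in treated liver. A second CF probe of the same contig was at least 2.63-fold higher, but was well above background on only 3 treated arrays and did not enter the test. A probe for the opposite strand of the contig was well above background on all arrays and was 17.0-fold higher in treated liver, with a log2 difference of 4.09 ± 0.64 (SE). It was also the brighter strand, with mean signals of 54 in controls and 994 in treated liver against 3.1 and 32 for UF_Msa_CF_125030. Which strand is transcribed was not tested. UF_Msa_AF_104788 of another contig was likewise measured in 4 of 4 treated and 0 of 4 control livers, at least 6.2-fold higher, and a second probe of that contig was at least 3.01-fold higher. Both of these probes were brightest in methoxychlor replicate 4, at log2 values of 1.002 and -0.09871. The other treated livers had -2.744 to -1.091 and -3.428 to -2.163, so these bounds lean partly on that array. The opposite-strand probe of this contig was well above background on 0 control arrays and 1 treated array and did not enter the test. In the other direction, UF_Msa_CF_119061 of contig01863 was 3.9-fold lower in treated liver. None of these differences passed the test across all probes. After another background correction (normexp), the log2 differences were 0.6265 for UF_Msa_CF_125030, 0.6105 for UF_Msa_AF_104788 and -0.2029 for UF_Msa_CF_119061. That correction adds an offset of 50, above the median signal of every array (5.93 to 10.86), which by construction shrinks the differences of dim probes.

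Of 17817 probes tested with limma, 0 were higher and 0 were lower in methoxychlor-treated liver at an adjusted p under 0.05. The smallest adjusted p was 0.203. At an unadjusted p under 0.05, 947 probes were higher and 377 were lower, 1324 in all against 890.8 that chance would give for independent probes. This excess changed with the array left out. The total was 3030 without control replicate 4, 1563 without control replicate 1 and 1117 without control replicate 3. It was 1098 without methoxychlor replicate 2 and 999 without methoxychlor replicate 3. No excess was left without control replicate 2 (836), methoxychlor replicate 1 (888) or methoxychlor replicate 4 (773). Leaving out an array also lowers the power of the test. Without control replicate 1, 860 probes were higher and 703 lower. The split was 738 higher to 508 lower with the deposited value table. It was 367 to 330 after normexp, whose offset shrinks the differences of dim probes, and which left 697 probes in all. The count of 0 did not hold under every setting: limma's array weights gave 1304 higher and 580 lower probes, and leaving out control replicate 4 gave 132 higher and 4 lower. Among simulated changes on these probes with the spread of these arrays, 5.07% of 2-fold, 54.2% of 4-fold and 78.3% of 8-fold changes were found.

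The 4 probes named here were those with the smallest unadjusted p in each direction. UF_Msa_CF_125030 and UF_Msa_AF_104788 were not well above background on any control array, with mean signals of 3.1 and 1.05 there. The same held for UF_Msa_CF_125751 on the treated arrays (2.01). The means and SDs of these groups are therefore values near the floor. Such an SD does not measure the spread between fish, and the p-values of these probes rest partly on it. UF_Msa_CF_125030 (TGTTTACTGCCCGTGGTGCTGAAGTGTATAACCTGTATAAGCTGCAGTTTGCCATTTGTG) had a log2 signal relative to the 75th percentile of -4.15 ± 0.67 (SD, n = 4) in controls and -0.64 ± 0.65 (SD, n = 4) in treated fish. The limma adjusted p was 0.203, and 4 of 4 treated arrays lay above all controls. UF_Msa_AF_104788 (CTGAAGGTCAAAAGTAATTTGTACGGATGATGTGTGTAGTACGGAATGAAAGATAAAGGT) had -5.63 ± 0.30 (SD, n = 4) in controls and -1.09 ± 1.56 (SD, n = 4) in treated fish, with a limma adjusted p of 0.338. UF_Msa_CF_119061 (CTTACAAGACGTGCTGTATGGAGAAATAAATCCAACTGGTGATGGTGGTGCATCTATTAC) was well above background on all arrays, at -0.46 ± 0.42 (SD, n = 4) in controls and -2.43 ± 0.27 (SD, n = 4) in treated fish. Its log2 difference was -1.96 ± 0.29 (SE), with a limma adjusted p of 0.338. The opposite-strand probe of contig01863 differed by only -0.27 ± 0.32 (SE), with a limma adjusted p of 0.874. UF_Msa_CF_125751 of contig21855 (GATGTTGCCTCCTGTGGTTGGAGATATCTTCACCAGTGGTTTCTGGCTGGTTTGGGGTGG) was well above background in 4 of 4 controls and in 0 of 4 treated livers. It was at least 1.31-fold lower in treated liver, with a limma adjusted p of 0.39, and its direction turned with normexp, where the log2 difference was 0.17. The opposite-strand probe of contig21855 was well above background on 0 control arrays and 1 treated array and did not enter the test. Its mean lay the other way, at -4.68 in controls and -3.61 in treated fish, with -1.041 in methoxychlor replicate 2. All 4 named probes passed an adjusted p of 0.05 with array weights, and all but UF_Msa_CF_125751 did so without control replicate 4.

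**Figure D1:**
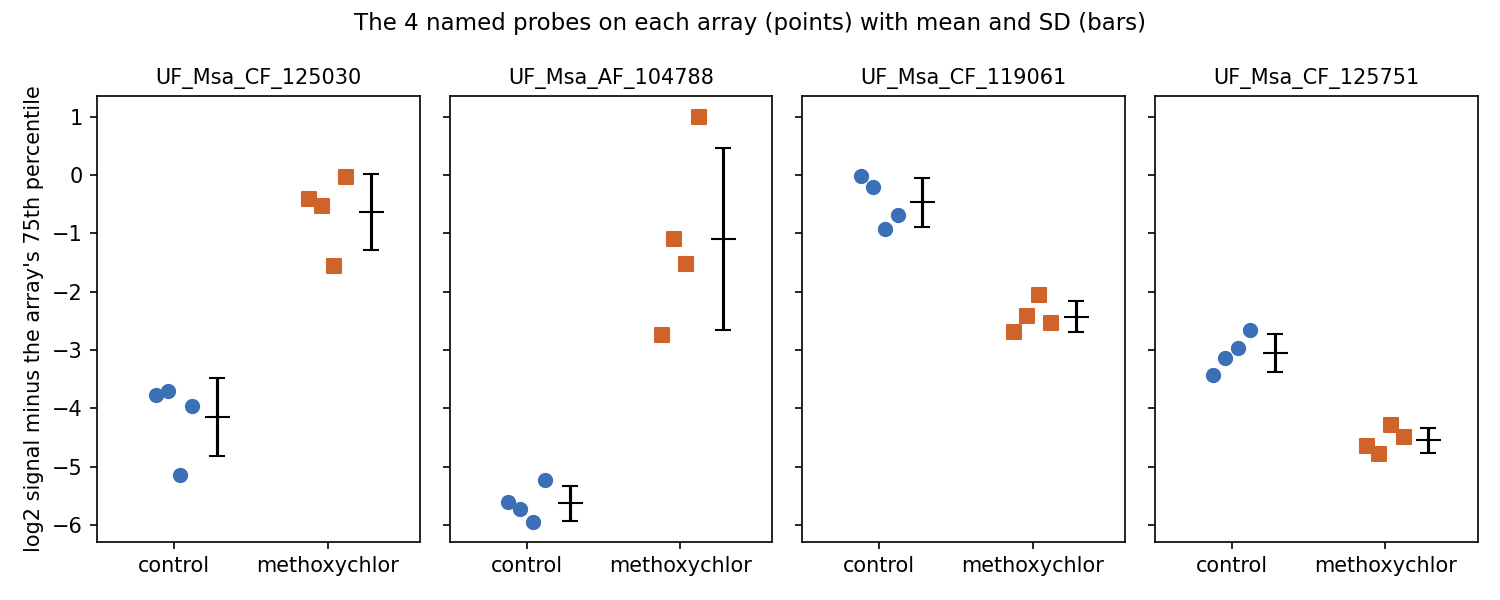
Log2 signal minus each array's 75th percentile (vertical axis) of the 4 named probes in control (circles) and methoxychlor-treated (squares) liver, 1 point per array, with the mean and SD of the 4 arrays of each group as bars. The groups do not overlap for any of the 4 probes, which were chosen for their small p, and UF_Msa_AF_104788 varied most between treated livers (SD 1.56). Control values of UF_Msa_CF_125030 and UF_Msa_AF_104788, and treated values of UF_Msa_CF_125751, were not well above background.

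Differences of at least 4-fold at an unadjusted p under 0.05 lay mostly in 1 direction, with 114 probes of 91 contigs higher and 9 probes of 7 contigs lower in treated liver. The 114 higher probes held 52 of class AF, 20 of class AM, 28 of class CF and 14 of class CM, the classes that the probe names give, and 69 of them were well above background on all 8 arrays. Of the higher probes 5, and of the lower probes 1, were not well above background on any array of 1 group, and with these at their bounds 111 higher and 8 lower probes stayed at 4-fold or more. Testing only probes well above background on all 8 arrays gave 74 higher and 0 lower. The median log2 difference of the 114 probes was 2.39 with bounds, and 1.04 after normexp. Over all probes tested after normexp, whose offset shrinks the differences of dim probes, 15 were at least 4-fold higher and 0 lower at an unadjusted p under 0.05. Without control replicate 4 there were 291 such higher probes and 34 lower, without control replicate 1 there were 71 and 27, without control replicate 3 there were 68 and 15, and without methoxychlor replicate 4 there were 75 and 3.

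Different probes of a contig gave similar differences. Over the 2178 contigs with a pair of tested AF probes, the log2 differences of the pair correlated with r = 0.888. The deviations of single arrays from their group means, which hold no mean difference between the groups, correlated as closely between the probes of a pair (r = 0.79 to 0.893). In 89 of these contigs both probes were higher at an unadjusted p under 0.05, in 15 both were lower, and in 0 both passed that p in opposite directions. Over all 2178 contigs, whatever their p, the pair had the same sign in 85.1%. AF and AM probes, which carry opposite strands, correlated with r = 0.479 over 2261 contigs, against 0.28 to 0.4 for the deviations of single arrays. These correlations run across contigs, which are not independent replicates, and the probes of a pair share the same 8 arrays.

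**Figure D2:**
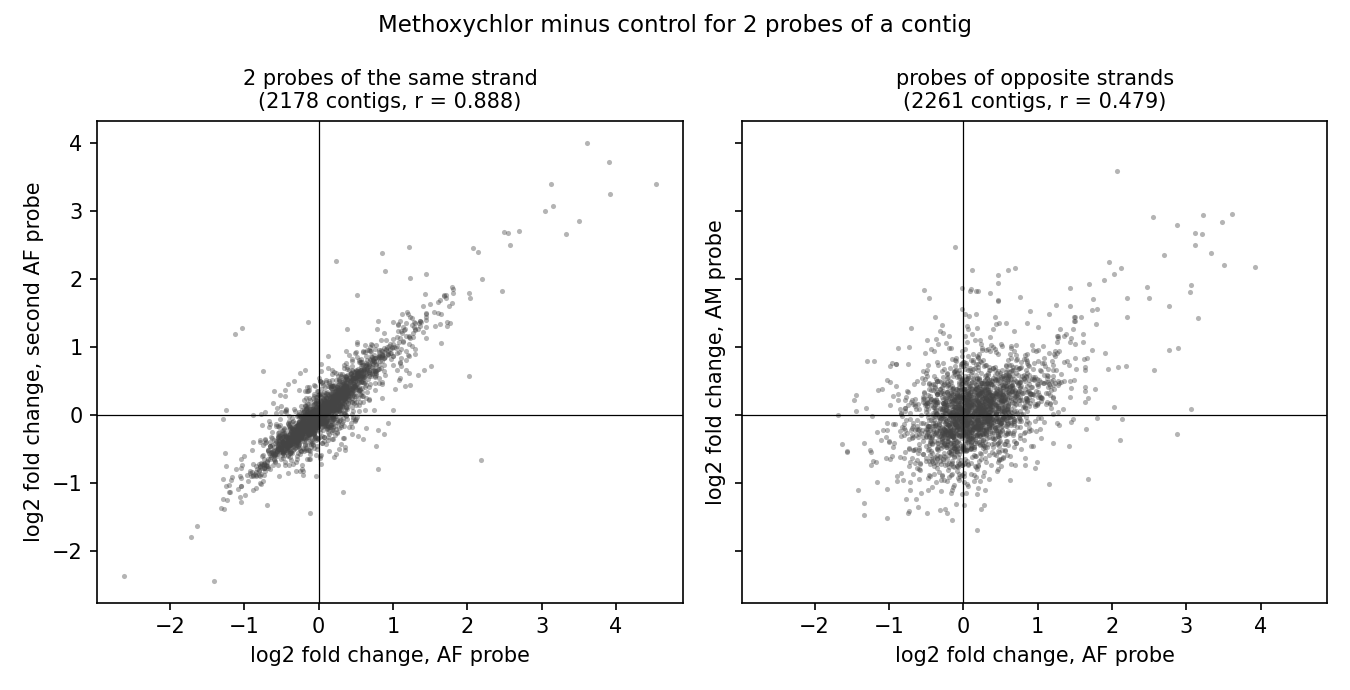
Log2 difference (methoxychlor minus control) of 1 probe of a contig against that of another, 1 point per contig, for a pair of AF probes (left, 2178 contigs, r = 0.888) and for an AF and an AM probe of opposite strands (right, 2261 contigs, r = 0.479). The 2 AF probes of a pair lie closer together than an AF and an AM probe. AM probes were also dimmer (median signal 3.1 against 22.3 for AF probes), so strand and signal were not separated.

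The livers of a group were less alike among controls. Pearson's r over 17486 probes was 0.862 to 0.954 between control arrays, 0.942 to 0.976 between methoxychlor arrays and 0.87 to 0.96 between arrays of different groups. The median SD of a probe was 0.61 on the log2 scale between control arrays and 0.338 between methoxychlor arrays, and 80.2% of probes varied more among controls. The median log2 variance ratio was -1.6, which did not pass an exact permutation test over the 35 splits of the arrays (two-sided p = 0.0571). Every control correlated better on average with the methoxychlor arrays than with the other controls, with the widest gap for control replicate 4 (mean r = 0.95 against 0.895). The values were 0.911 against 0.893 for control replicate 1, 0.946 against 0.932 for control replicate 2 and 0.902 against 0.897 for control replicate 3.

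**Figure D3:**
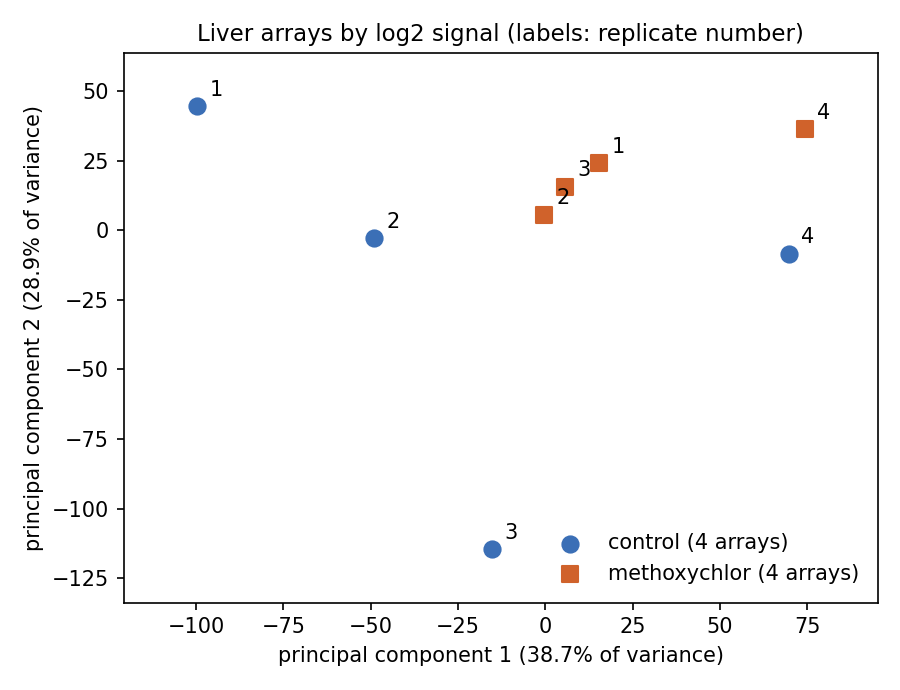
The 8 arrays on the first principal components of the log2 signals, with component 1 (38.7% of the variance) on the horizontal and component 2 (28.9%) on the vertical axis, controls as circles, methoxychlor as squares, and the replicate number beside each. Neither axis separates the groups, the controls are spread widely, and control replicate 4 lies near methoxychlor replicate 4.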

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

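No array lay far from the other arrays of its group by Dixon's test on 5 array measures, the 4 named probes or the mean of the 4-fold higher probes. The 3 patterns below were noticed in the data. The counts over other splits (except that without control replicate 4), the spike-in tests, the test of array brightness and the test of control replicate 4's label were chosen after the result was seen.

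Control arrays differed more among themselves than methoxychlor arrays, with a median log2 variance ratio of -1.6. Spot unevenness is argued against only for 7515 probes spotted 2 times, where repeat spots held 3.45% of the variance between control arrays. Spots marked as outliers were left out of that test, and it cannot cover probes spotted once. A cause in 1 odd control is argued against too, since the ratio stayed at -1.09 or further from 0 without any of them. Chance was not excluded, as 2 of 35 splits gave a ratio as far from 0 (real -1.603, highest other 1.998 in size), and the spike-in controls left labelling and hybridisation open (median ratio 0.421, range -2.03 to 2.01). A wrong label on control replicate 4 stays open, though the ratio was still -1.09 without it: over the 100 probes with the smallest p in a fit without it, it lay at 1.17 on a scale from the other controls (0) to the methoxychlor mean (1), and 85 of the 100 lay above 0.75. A swap with a treated sample stays open too. Exchanging control replicate 4 with methoxychlor replicate 1, 2 or 3 gave 2121, 3150 or 2617 probes at an unadjusted p under 0.05 against 1324. The exchange with methoxychlor replicate 4 gave 654. Exchanging control replicates 3 and 4 together with 2 of methoxychlor replicates 1 to 3 gave 2126, 2207 and 2517. High counts are therefore not particular to an exchange of control replicate 4. With array weights all 4 exchanges of control replicate 4 alone gave fewer calls at an adjusted p under 0.05 than the real labels. They gave 49 to 1438 against 1884, the highest with methoxychlor replicate 4. The measures thus do not settle on a partner, and a control fish in a similar liver state may give the same values.

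More probes lay higher than lower in treated liver at an unadjusted p under 0.05 (71.5% higher), but 55% were higher without control replicate 1 and 63.7% without control replicate 3. Chance was not excluded for the imbalance, since in 8 of 35 splits as large a share lay in 1 direction (highest other 76.9%), nor for the number of probes, which 7 of 35 splits reached (real 1324, highest other 3150). The highest number comes from the exchange of control replicate 4 with methoxychlor replicate 2, and no test told a structure of the samples from a wrong label. Scaling was not decided, with 59.2% higher in the deposited values and 63.9% or more under the other scalings run, while normexp gave 52.7%. Bright spike-ins differed by at most 0.121 on the log2 scale between slides, which leaves open a slide effect on fish RNA that cannot be told apart from treatment.

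The probes at least 4-fold higher in treated liver also varied together between fish of a group, with a mean correlation of deviations of 0.541 over 107 probes. It was 0.517 with 1 probe per contig, and at most 0.0816 in 1000 sets matched on level and spread. The matched sets were not chosen for a difference in 1 direction, as this set was. They therefore do not show how much of the correlation that choice brings. Shared probe sequence is argued against, as 4.4% of their contigs had a probe that shared 20 bases with a probe of another. Contig sequences were not compared, so contigs of 1 transcript or gene family stay open. A brightness shift common to all probes was not put to a test, since scaling to each array's 75th percentile had already removed it. Quantile normalization goes further and gives all arrays 1 distribution of signal. The mean correlation was then 0.505, against at most 0.0726 in matched sets. A difference between arrays in that distribution alone is therefore argued against. Quantile normalization cannot remove an effect on some probes only. In each group the array in position 4, with the lowest 75th percentile of signal, had the highest set mean (1.0 and 3.23). An effect of low signal or position stays open. Chance in which fish fell in which group was not excluded for the number of probes: 4 of 35 splits gave as many at 4-fold (real 123 in both directions, highest other 218). The splits count probes and do not test their correlation. The mean of the set was -1.34, 0.0226, -1.34 and 1.0 in control replicates 1 to 4 and 1.48 to 3.23 in treated livers, and the set was chosen for that difference. No biological explanation of the variation between fish of a group was tested.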

How the results depend on the processing

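The threshold, array weights, replicate block and exclusions were planned before the data were examined, and contig means, array weights per group and spike-in scaling were chosen afterwards. Against 0 higher and 0 lower probes, array weights gave 1304 and 580, and an unadjusted p under 0.01 with at least 1.5-fold gave 243 and 48, a looser threshold by construction. Leaving out 1 array gave 0 to 132 higher and 0 to 4 lower probes, with both highest values from control replicate 4 and 1 higher probe without control replicate 3. The count was 0 in both directions for normexp, quantile, median and spike-in scaling, both filters, marked spots kept, trend and robust, the deposited table, contig means and array weights per group. Array weights ranged from 0.261 (control replicate 4) to 5.19 (control replicate 2), so that fit rests largely on 1 control. With array weights, 1 of 35 splits gave as many probes, the real one (1884, highest other 1438), and without control replicate 4 likewise 1 of 35 (136, highest other 1), which does not allow for the choice of the array left out. For the fit of all arrays such a count decides nothing, since 35 of 35 splits must give at least its 0 (highest other 2). The cause of these shifts was not tested.

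With the replicate number as a block (replicate block), 2 probes were higher and 0 lower, and UF_Msa_CF_125030 was 1 of them (adjusted p 0.0352, over all its alternatives 0.0107 to 0.712). In both groups the replicate number was also the position on the slide, so this block cannot tell a pairing of samples from a position effect. Deviations of same-numbered arrays correlated at 0.14, 0.09, 0.03 and 0.54 for numbers 1 to 4. Of the 8 arrays, 2 correlated best with their own number, so most arrays were not paired by it.

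Of the alternatives for the 4 named probes, 68 kept direction and side of the threshold, 8 passed it in the same direction and 1 reversed: UF_Msa_CF_125751 with normexp, at 0.1655, and the cause was not tested. Normexp lowered the log2 differences of the other 3 to 0.6265, 0.6105 and -0.2029; its offset of 50 exceeds the median signal of every array (5.93 to 10.86). Signal over background limits the dim probes, since 13614 of 17817 were well above background on all arrays. Slide and scan blocks, gene lists, cell type markers and the choice of probe per gene were not run, because each slide held 1 group and no probe has a gene name.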

Other observations

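Probes of the 4 classes given by the probe names were detected to different extents. On an average array, 73.7% ± 2.87 (SD over 8 arrays) of AF probes were well above background, against 39.4% ± 3.54 of AM, 46.5% ± 3.1 of CF and 45.3% ± 3.05 of CM probes. The AF share was 73.8% on control and 73.7% on methoxychlor arrays.

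For opposite-strand probes of a contig, the treatment differences correlated at 0.479 in class A and 0.361 in class C. Deviations of single arrays within a group also correlated between strands, at 0.28 to 0.4 in class A and 0.0737 to 0.294 in class C. These values lay below those of the treatment differences. Some agreement between strands was therefore present within groups, which include the treated fish. In 29 class A contigs both strands were higher at an unadjusted p under 0.05, in 3 both were lower and in 1 they went opposite ways. In class C the numbers were 13, 2 and 3. Contigs are not independent replicates, and no strand-specific check of the labelling was run.

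The arrays in position 4 of the slides, control replicate 4 and methoxychlor replicate 4, had the lowest 75th percentile of signal of their slides, 39.08 and 36.3, and deviated together from their groups with a correlation of 0.54 over probes. Methoxychlor replicate 4 is also the array with rounded values. GC content was 45% in the median for the 4-fold higher probes and 45% for all tested probes.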
